A study of Pseudomonas aeruginosa AES-1R with 4 samples.

How the data were processed

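RNA from biofilms of Pseudomonas aeruginosa AES-1R was sequenced in 4 samples, 2 treated with PBS and 2 with 2 mM GSH for 8 h, grouped by the sample titles. Per the labels' protocols, cultures were pooled in technical triplicate before RNA extraction, ribosomal RNA was depleted with a Ribo-Zero Gold kit for bacteria, and libraries were made with a stranded TruSeq kit and sequenced as paired-end reads on a NextSeq instrument. The submitters' processing notes name Bowtie2 2.2.5, SAMtools 0.1.19 and HTSeq 0.6.1, without their roles. The strand setting and the treatment of overlapping genes during counting are not given in the sources used here, nor is whether a count stands for a read or a read pair. Reads from a gene and from an overlapping gene on the other strand can therefore not be separated here, and genes with near-identical copies, such as the phenazine operon, carry uncertain counts.

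The files deposited by the authors hold whole-number, unnormalized read counts for 5883 coding sequences in each sample. A deposited AES-1R annotation gives start and end positions, counted from 1, for 5959 features, of which 5894 are coding sequences, 64 transfer RNAs, 1 a transfer-messenger RNA and 0 ribosomal RNAs. Of the counted coding sequences 1726 have a gene symbol in it, and the reference gene table of strain PAO1 added 0 symbols. Positions are those of the deposited annotation. Closing lines that name no gene were kept out of library sizes and tests. Of all reads counted, coding sequences held 68.5% and 66.8% in PBS replicates 1 and 2, and 74.1% and 55.2% in GSH replicates 1 and 2. The rest was mostly reads in no annotated gene, and 4.37% to 6.45% were reads that overlapped several genes. The 10 most abundant genes held at most 7.21% of them. With 2 samples per group the smallest two-sided exact permutation p of a single value is 0.333, so no such test can reach 0.05, and the tests pool the spread across genes.

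Counts were analysed in R 4.3.3. The main test was edgeR 4.0.16's quasi-likelihood F-test (glmQLFit and glmQLFTest) with TMM scaling, after filterByExpr at its default minimum count of 10, which left 5866 genes and removed 17. Calls required a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken from the fold change and its F statistic, and the common biological coefficient of variation was 13.7% on 2 residual degrees of freedom. Values per group are CPM, counts divided by TMM-scaled library size. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, two-sided, over lists with at least 4 tested members, and adjusted over the 34 lists. They held 921 symbols, of which 616 matched a counted gene, 612 features by the annotation's symbol and 15 by a protein name in the product text. Coverage differed between lists. Type VI secretion had 62 symbols and 12 tested members, zinc starvation 18 and 5, copper 25 and 8, and RND efflux pumps 38 and 16. Results for such lists describe the matched members only, not the whole system. A product name shared by several genes was matched to none of them, which was decided once the annotation had been read. Counts of list members are given over all genes tested and adjusted over the list alone, and where the text gives a single count both were the same.

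The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 12 largest rises and 12 largest falls among called genes with an annotated product, a mean of at least 20 counts per sample and both GSH values on the same side of both PBS values, and up to 4 members of each list with the smallest adjusted p. pvdS, pvdD_1, fpvB, napE and napF, and the segment of neighbouring genes, fall outside that rule and were chosen after their values were seen.

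The gene test was tested on simulated data, in 5 sets with 200 changed genes among 5866, drawn from the means, dispersions and library sizes of these samples. It called 31.6% of genes changed 1.5-fold, 90.2% of those changed 2-fold and 99.7% of those changed 4-fold, and 6.5% of its calls were unchanged genes. In a further 5 sets with 3 lists shifted 2-fold, camera with the preset correlation called 15 of 15 shifted lists and 0 of 155 others, and with an estimated correlation 4 of 15 and 0 of 155. Genes were drawn independently there, so these sets do not test how the preset correlation fares with correlated genes, for which it can call too many lists. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, removal of the 10 most abundant genes, the replicate number as a block, a robust fit, a fold threshold, fry, an estimated correlation and leaving out each sample in turn. List member counts under each alternative, and list tests with library totals, upper quartile scaling, a mean of at least 50 counts, a robust fit or the 10 most abundant genes removed, were added after seeing the data.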

Results

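RNA sequencing was used to compare mature biofilms of Pseudomonas aeruginosa AES-1R, a clinical strain of this opportunistic pathogen, with and without glutathione (GSH), a thiol peptide found in host tissue. Biofilms were grown for 72 h in an artificial cystic fibrosis sputum medium, given 2 mM GSH or phosphate-buffered saline (PBS), and collected after a further 8 h, at a culture age of 80 h. The comparison addressed which transcripts of an established biofilm differ after exposure to GSH. Each group held 2 samples, referred to as PBS replicates 1 and 2 and GSH replicates 1 and 2. Reads assigned to coding sequences numbered 26375408 and 22075645 in PBS replicates 1 and 2, and 25947361 and 16921522 in GSH replicates 1 and 2. Reads in no annotated gene made up 25.6% and 27.8% of all reads counted in the PBS samples, 18.9% in GSH replicate 1 and 40.1% in GSH replicate 2. The widest 95% Wilson interval of such a share spanned 0.0352 percentage points, which covers counting error only. Log2 CPM (counts scaled to library size) correlated across genes with a Pearson r of 0.989 between the PBS samples and 0.994 between the GSH samples, against 0.970 to 0.986 between samples of different groups. The first principal component held 73.0% of the variance and placed PBS replicate 2 at -23.3, PBS replicate 1 at -9.17, GSH replicate 1 at 14 and GSH replicate 2 at 18.4. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 139 between the PBS samples and 61.1 between the GSH samples. Every RNA sample came from pooled cultures. Beyond the labels nothing states that the samples of a group were grown separately, so the p-values measure the spread between these samples.

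With GSH, most of the genes measured for pyoverdine, the main siderophore of this species, were higher, as were some ribosomal protein and denitrification genes, although these lists were called only with the preset correlation of the list test. In a 62.6 kb chromosomal segment with genes for glycogen and trehalose metabolism, singled out after its values were seen, most genes were lower. Of 5866 coding sequences tested, 186 were higher and 184 lower with GSH in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05, 2 samples per group). At least 2-fold changes were found for 95 of the higher and 106 of the lower genes, and the median absolute log2 fold change of the 370 called genes was 1.04. The values of the groups were fully separated for all 370 called genes, and for 3293 of all tested genes (56.1%), where chance alone gives 33.3% for 2 samples against 2. Products of 81 called genes were annotated as hypothetical or left without a name. Of 34 gene lists, 6 were higher and 2 lower with GSH in the camera test with a preset correlation between genes. With an estimated correlation camera called 0 lists (0 at an unadjusted p under 0.05, smallest adjusted p = 0.843). Fry's directional test called 0 as well (6 at an unadjusted p under 0.05, smallest adjusted p = 0.202), while its mixed test, for change in either direction, called 2, general secretion (adjusted p = 0.00110) and RND efflux pumps (0.00189). With library totals as the only scaling, 160 genes were higher and 240 lower, 40.0% of calls being higher against 50.3%. The median log2 fold change of all genes then moved from -0.01 to -0.10. The counts depended on single samples: 622 genes were higher and 473 lower without PBS replicate 1, and 207 and 197 without PBS replicate 2. They numbered 147 and 100 without GSH replicate 1, and 60 and 75 without GSH replicate 2. The lists called higher and lower fell to 2 and 0 without GSH replicate 1.

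**Figure D1:**
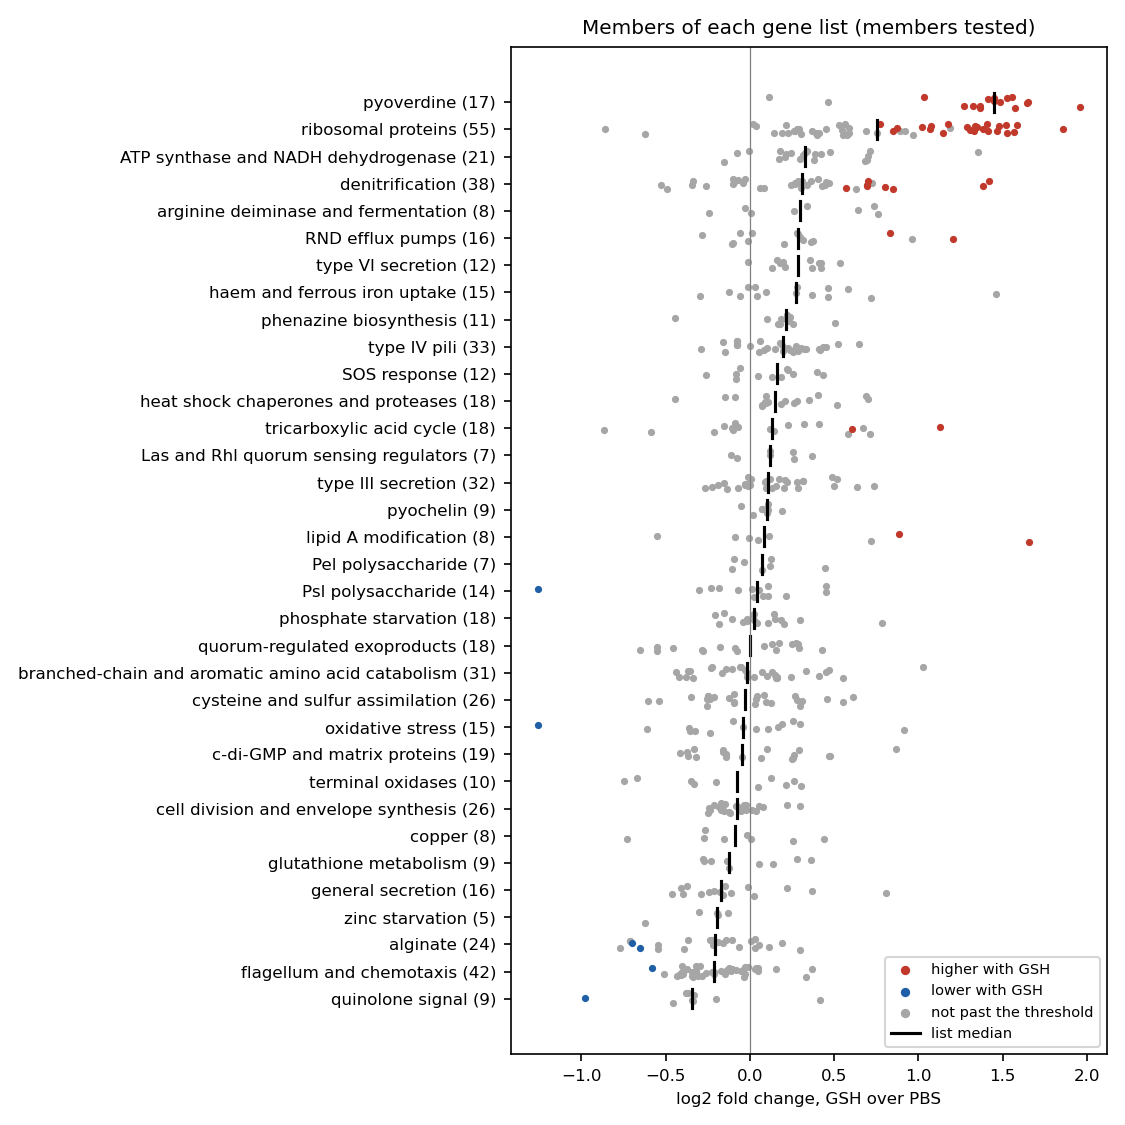
Log2 fold change (GSH over PBS, horizontal axis) of members of the gene lists, with list names and numbers of tested members on the vertical axis. Red and blue points are members higher and lower with GSH, grey points did not pass and black bars are medians. The pyoverdine list had the highest median, 1.45, followed by the ribosomal proteins at 0.76.

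Pyoverdine genes rose as a group, with 15 of the 17 measured members higher, 0 lower and 2 not past the threshold, and the same number, 15, higher when adjusted over the list alone. The list's median log2 fold change was 1.45 (camera adjusted p = 5.23e-21; adjusted p = 0.843 with an estimated correlation). The PBS samples also differed in these genes, by a median of 0.76 (PBS replicate 1 minus PBS replicate 2), and the list's median was 1.84 without PBS replicate 1 and 1.11 without PBS replicate 2. The biosynthesis gene pvdE, at positions 5143981 to 5145633 of the deposited AES-1R annotation, went from 74.7 ± 27.6 to 290.5 ± 66.1 CPM (mean ± SD, n = 2), a log2 fold change of 1.96 ± 0.27 (SE; edgeR adjusted p = 0.00749). pvdA, the ornithine hydroxylase of the pathway (5129441 to 5130772), rose from 252.7 ± 93.0 to 742.2 ± 59.8 CPM, by 1.55 ± 0.26 on the log2 scale. The receptor gene fpvA rose by 1.49 ± 0.21 (edgeR adjusted p = 0.00760). Rises were also found for the maturation gene pvdP (1.45 ± 0.21), pvdO (1.65 ± 0.26) and the outer membrane export gene opmQ (1.03 ± 0.14). The sigma factor gene pvdS, whose product directs transcription of pyoverdine genes, rose by 1.32 ± 0.26 (edgeR adjusted p = 0.0280), but was not called without GSH replicate 2 (0.0737) or in a robust fit (0.0524). It lies in a cluster (5194250 to 5209889) in which 8 of 9 genes were higher, of which 2 were called without GSH replicate 1, 1 without GSH replicate 2 and 1 in the robust fit. The peptide synthetase genes pvdI (5160769 to 5171835) and pvdD_3 (5154559 to 5160756) rose by 1.57 ± 0.31 and 1.64 ± 0.37. These synthetases share similar modules, so reads could be split between them and their values are less certain. Between the named pyoverdine genes, AES1R_04843, annotated as a putative dipeptidase (5139203 to 5140561), had the largest rise among annotated genes, from 85.9 ± 48.5 to 390.1 ± 55.9 CPM, a log2 fold change of 2.18 ± 0.35 (edgeR adjusted p = 0.0128). Its neighbour AES1R_04844, an aminotransferase, rose by 1.89 ± 0.28. The members that did not pass were pvdD_1, a fragment elsewhere on the chromosome (0.46 ± 0.20), and the second receptor gene fpvB (0.11 ± 0.13). No member of the lists for pyochelin, the other siderophore (9 measured members, median 0.10, camera adjusted p = 0.695), or for haem and ferrous iron uptake (15 members, median 0.27, camera adjusted p = 0.190) passed the gene test. The bacterioferritin gene bfrB, in the latter list, had a log2 fold change of 1.46 ± 0.41 (edgeR adjusted p = 0.0764). Of the pyoverdine genes 9 were higher without GSH replicate 2. pvdI (edgeR adjusted p = 0.0782) and pvdD_3 (0.107) no longer passed without GSH replicate 1, nor did they without GSH replicate 2 (0.0525 and 0.0503), and pvdD_3 did not in the robust fit (0.0645). Without PBS replicate 1 the log2 fold changes of AES1R_04843 and pvdD_3 were 2.92 and 2.33. Among the fits that left out a sample, the haem list was called higher without GSH replicate 2 (camera adjusted p = 0.0177). The pyochelin list was called higher without PBS replicate 1 (median 0.61, camera adjusted p = 0.0149), but its direction turned without PBS replicate 2 (median -0.32, 0.108).

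Ribosomal protein genes were higher with GSH in 23 of 55 measured members and lower in 0, with 32 not past the threshold, and 34 were higher when adjusted over the list alone. Most of the 23 calls came from a single cluster (5314528 to 5326341), a grouping made after the results were seen. In it 21 of 25 genes were higher, all 21 encoding ribosomal proteins. The median log2 fold change of the list was 0.76 (camera adjusted p = 5.05e-20; adjusted p = 0.843 with an estimated correlation), and 53 of the 55 values lay above 0. The largest rise was that of rplW, encoding 50S protein L23 (5324794 to 5325093), from 114 ± 63.1 to 413.6 ± 61.7 CPM (mean ± SD, n = 2), a log2 fold change of 1.86 ± 0.35 (SE; edgeR adjusted p = 0.0220). rpsC, encoding 30S protein S3 (5322625 to 5323311), rose by 1.58 ± 0.33 and rplV, encoding L22 (5323324 to 5323656), by 1.57 ± 0.26 on the log2 scale. rpmC rose by 1.35 ± 0.20, rpsS by 1.41 ± 0.23 and rpsM by 1.07 ± 0.18. The secretion gene secY, which lies in the same cluster, had a log2 fold change of 0.81 ± 0.22 (edgeR adjusted p = 0.0720) and did not pass, nor did any other of the 16 measured members of the general secretion list (median -0.17, camera adjusted p = 0.432). In the heat shock list, 0 of 18 members passed (median 0.15, camera adjusted p = 0.211), with groEL at 0.70 ± 0.24 (edgeR adjusted p = 0.125). In the fit without GSH replicate 2, 7 ribosomal protein genes were higher, and rplW (edgeR adjusted p = 0.0503), rpsC (0.0603) and rpsM (0.0683) no longer passed. rpsC also did not pass without GSH replicate 1 (0.0617) or in a robust fit (0.0536). Without PBS replicate 1, rplW and rpsC stood at 2.57 and 2.22, and 2 ribosomal protein genes were lower. The heat shock list was called without PBS replicate 2 (camera adjusted p = 2.04e-04).

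Genes of denitrification, the stepwise reduction of nitrate to nitrogen gas, were higher in 8 of 38 measured members, lower in 0 and not past the threshold in 30, with 12 higher and 2 lower when adjusted over the list alone. The 8 calls came largely from the nitrite reductase cluster (1352340 to 1361330), not from all steps of the pathway. In that cluster 7 of 11 genes were higher, among them nirN, nirJ, nirL, nirF, nirM and nirS. The list's median log2 fold change was 0.31 (camera adjusted p = 5.52e-04; adjusted p = 0.843 with an estimated correlation). dnr, a transcriptional regulator of denitrification genes (1367246 to 1367929), rose from 39.1 ± 0.827 to 104.8 ± 2.79 CPM (mean ± SD, n = 2), a log2 fold change of 1.42 ± 0.13 (SE; edgeR adjusted p = 0.00182). nirS, the nitrite reductase itself (1359624 to 1361330), rose by 0.85 ± 0.16, and nirL and nirF, which serve the synthesis of its haem d1 cofactor, by 1.38 ± 0.22 and 0.80 ± 0.17. The periplasmic nitrate reductase genes napF (-0.53 ± 0.14) and napE (-0.49 ± 0.15) had lower values that passed only over the list. ATP synthase and NADH dehydrogenase genes were higher as a list (median 0.33, camera adjusted p = 0.00398; adjusted p = 0.843 with an estimated correlation). Of its 21 members 0 passed in the gene test or when adjusted over the list alone, the largest value being 1.35 ± 0.35 for nuoI (edgeR adjusted p = 0.0603). In the tricarboxylic acid cycle list (18 members, median 0.13, camera adjusted p = 0.351) the citrate synthase gene gltA rose by 1.13 ± 0.20 and the malate oxidoreductase gene mqoB by 0.61 ± 0.14. Adjusted over that list alone, 5 members were higher and 2 lower, among the latter the aconitase gene acnA at -0.87 ± 0.22 (edgeR adjusted p = 0.0597 over all genes). The terminal oxidase list had 0 of 10 members past the threshold and 2 lower when adjusted over the list alone, with the cyanide-insensitive oxidase gene cioB at -0.67 ± 0.17 (edgeR adjusted p = 0.0571). In the list for arginine deiminase and fermentation, 0 of 8 members passed and 3 were higher when adjusted over the list alone, with arcA at 0.76 ± 0.22 (edgeR adjusted p = 0.0841). Without GSH replicate 1 neither the denitrification list (adjusted p = 0.0643) nor the ATP synthase and NADH dehydrogenase list (0.101) was called, nor were nirS (0.108), nirF (0.202) or mqoB (0.205). Higher denitrification genes numbered 2 in that fit and 4 without GSH replicate 2, and without PBS replicate 1 there were 2 lower. mqoB was also lost without PBS replicate 1 (0.0525), PBS replicate 2 (0.0515) or GSH replicate 2 (0.188), with library totals (0.0818) and with upper quartile scaling (0.0501). In the fit without GSH replicate 2, gltA was lost (0.0603) and the arginine deiminase list called (0.0200).

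The largest fall with GSH was that of AES1R_05784, annotated as a lysozyme inhibitor (6196340 to 6196807), which went from 1128 ± 68.3 to 152.2 ± 9.70 CPM (mean ± SD, n = 2), a log2 fold change of -2.89 ± 0.18 (SE; edgeR adjusted p = 7.74e-04). Of the 12 largest falls among annotated genes, 8 lay between positions 2331093 and 2393724 of the deposited annotation. In that segment, singled out after its values were seen, 51 of 65 genes fell, 0 rose, and the median log2 fold change was -1.32. The glycogen synthase gene glgA (2369930 to 2371534) fell from 214.2 ± 19.3 to 58.4 ± 7.0 CPM, by 1.87 on the log2 scale (SE 0.16; edgeR adjusted p = 0.00155). Its neighbours AES1R_02244, a putative glycosyl hydrolase, and AES1R_02243, a putative 4-alpha-glucanotransferase, had log2 fold changes of -2.06 ± 0.17 and -1.89 ± 0.15. The segment also held ligD, an ATP-dependent DNA ligase gene (2336255 to 2337013; -2.21 ± 0.26), and the putative histidine kinase gene AES1R_02215 (2334123 to 2334512; -2.21 ± 0.19), whose last 94 bases overlap a gene on the other strand and are less certain. Further falls in the segment were those of the hemerythrin-domain gene AES1R_02251 (-1.93 ± 0.22), the putative magnesium transporter gene AES1R_02229 (-1.86 ± 0.21) and the aldehyde dehydrogenase gene AES1R_02249 (-1.81 ± 0.21). katE, a catalase gene of the segment, fell by 1.26 (SE 0.16, edgeR adjusted p = 0.00558). The segment's non-heme catalase gene katN (2387594 to 2388478) stood at -0.61 ± 0.15 and did not pass (edgeR adjusted p = 0.0571). katE was the only member of the oxidative stress list to pass out of 15, with 2 lower when adjusted over the list alone. The more abundant catalase gene katA, also in the list, went the other way, from 3035 ± 1732 to 5716 ± 740 CPM. Its log2 fold change of 0.91 ± 0.39 did not pass (edgeR adjusted p = 0.205). That list had a median of -0.04 (camera adjusted p = 0.456). Elsewhere, the adjacent genes AES1R_05066, of the CsbD family (5400557 to 5400754), and AES1R_05067, a transport-associated protein (5400804 to 5401148), had log2 fold changes of -1.97 ± 0.22 and -1.92 ± 0.20. phnP, of the carbon-phosphorus lyase operon (3830951 to 3831721), stood at -1.84 ± 0.14, while 0 of 18 members of the phosphate starvation list passed (median 0.03, or -0.07 with library totals, camera adjusted p = 0.695). Of the 51 genes that fell in the segment, 51 were still called without either PBS sample, 44 without GSH replicate 1 and 37 without GSH replicate 2.

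**Figure D2:**
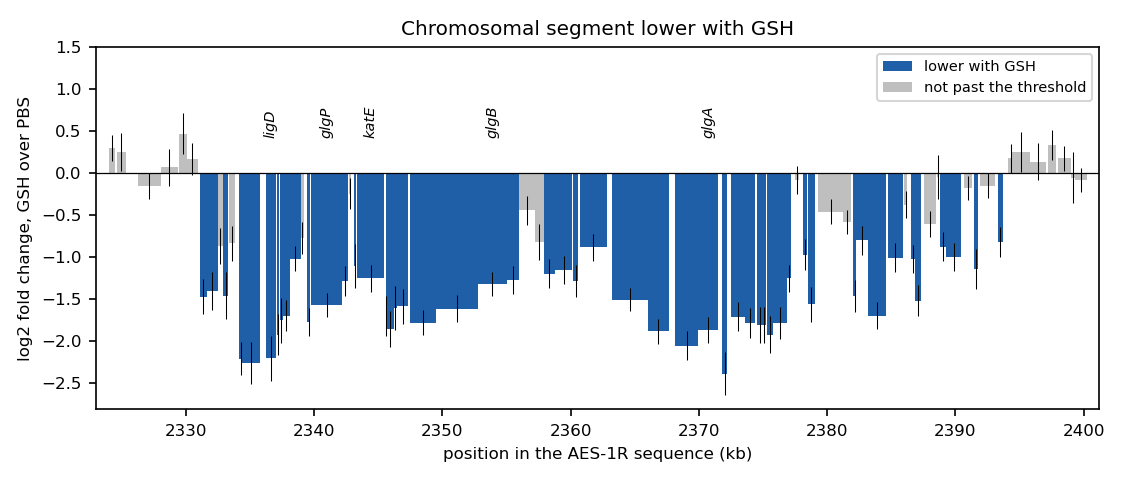
Log2 fold change (GSH over PBS, vertical axis) of each gene by its position in kb on the deposited AES-1R sequence, with the segment and its flanks drawn to scale and black lines showing standard errors. Within the segment 51 of 65 genes were lower with GSH and 0 higher.

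**Figure D3:**
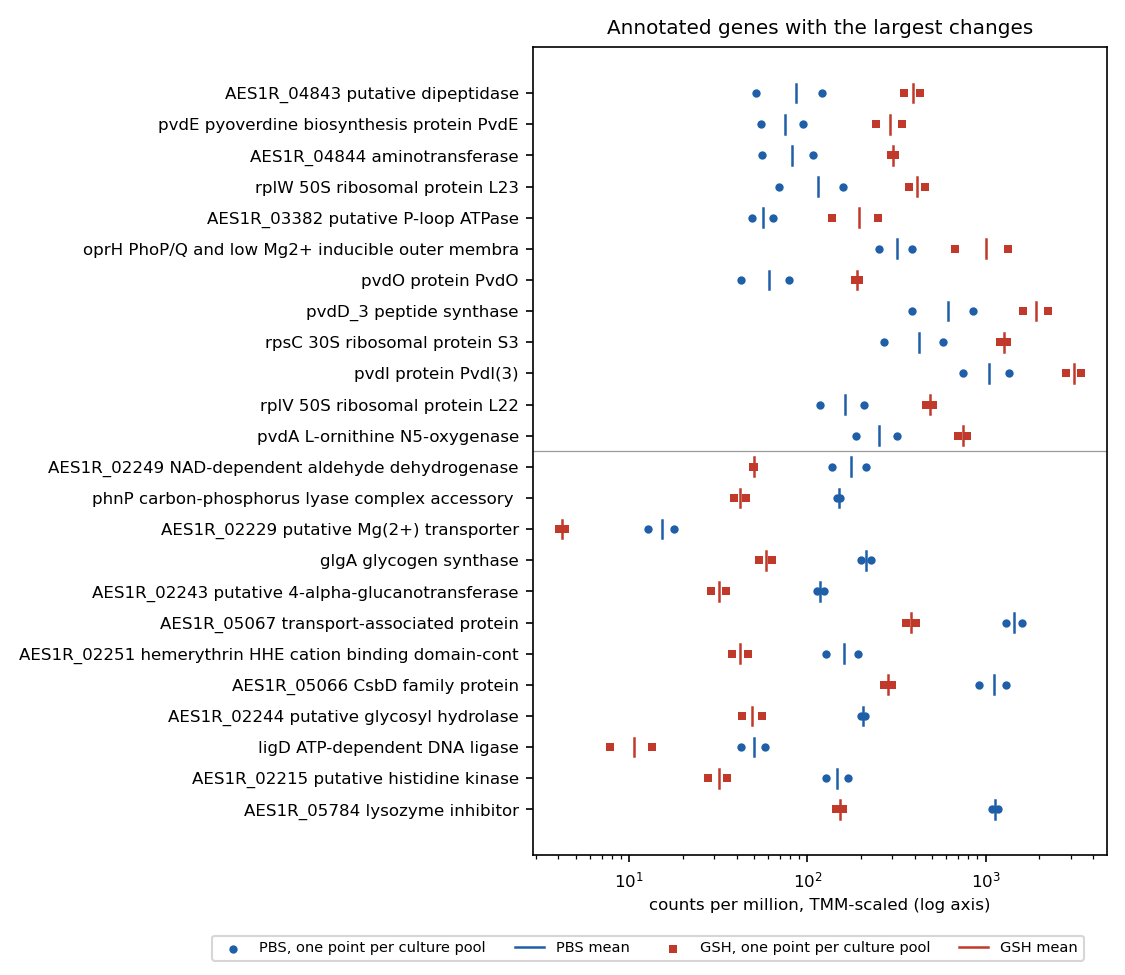
CPM on a log axis for each sample, as points, with group means as vertical lines, for the 12 largest rises and 12 largest falls among annotated genes. In each row both GSH points lie on the same side of both PBS points.

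oprH, an outer membrane protein gene of the PhoP and PhoQ regulon (571171 to 571773), rose from 319.7 ± 97.4 to 1008 ± 470.7 CPM (mean ± SD, n = 2), a log2 fold change of 1.66 ± 0.34 (SE; edgeR adjusted p = 0.0332). lpxO2, a lipid A hydroxylase gene, rose by 0.88 ± 0.19. They were the only 2 of the 8 lipid A modification genes past the threshold, against 3 higher when adjusted over the list alone, and the list's median was 0.08 (-0.01 with library totals; camera adjusted p = 0.258). In the list of RND efflux pumps, a family of multidrug exporters, mexD and oprJ of the mexCD-oprJ operon rose by 0.83 ± 0.15 and 1.21 ± 0.14, 14 of 16 members did not pass, and 3 were higher when adjusted over the list alone. That list was higher (median 0.28, camera adjusted p = 0.0347; adjusted p = 0.843 with an estimated correlation), as was the type VI secretion list (median 0.28, camera adjusted p = 0.0436; adjusted p = 0.843 with an estimated correlation), in which 0 of 12 members passed alone. With library totals the type VI secretion list was not called (camera adjusted p = 0.0603). AES1R_03382, a putative P-loop ATPase (3540786 to 3543779), rose by 1.78 ± 0.28 on the log2 scale (edgeR adjusted p = 0.0116). Flagellum and chemotaxis genes were lower as a list (median -0.21, camera adjusted p = 0.0237; adjusted p = 0.843 with an estimated correlation), with 1 of 42 members past the threshold, the rod protein gene flgF at -0.58 ± 0.14, and 0 when adjusted over the list alone. The alginate list was also lower (median -0.21, camera adjusted p = 0.0237; adjusted p = 0.843 with an estimated correlation), with 2 of 24 members past the threshold and 4 when adjusted over the list alone. These members were regulators, algB, an activator of alginate synthesis (-0.70 ± 0.15), and mucC of the algU operon (-0.65 ± 0.14), while mucA, the anti-sigma factor gene of that operon, stood at -0.77 ± 0.20 (edgeR adjusted p = 0.0579). Type IV pili (0 of 33 members, median 0.19, camera adjusted p = 0.110) and type III secretion (0 of 32, median 0.11, camera adjusted p = 0.351) were not called. Without GSH replicate 1 none of the efflux pump (camera adjusted p = 0.128), type VI secretion (0.231), flagellum (0.109) and alginate (0.0546) lists was called. The genes mexD (0.116), flgF (0.244), algB (0.0695) and mucC (0.127) were lost. Without PBS replicate 1 the efflux (0.137) and flagellum lists (0.394) were lost and type IV pili called (0.0423). Without PBS replicate 2 the type VI (0.159) and alginate lists (0.0563), flgF (0.0815), algB (0.0518) and lpxO2 (0.0554) were lost. In the fit without GSH replicate 2, oprH (0.0905), lpxO2 (0.181), flgF (0.188), algB (0.252) and mucC (0.212) were lost and type IV pili called (0.0239). On all samples, oprH was lost in a robust fit (0.0578), and flgF in limma-voom (0.0518) and with upper quartile scaling (0.0521).

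Lists for biofilm matrix, quorum sensing and thiol metabolism had few or no members past the threshold. Of the Psl polysaccharide list 1 of 14 members fell, pslN at -1.26 ± 0.18, which the deposited annotation describes as a putative DNA topoisomerase, and the list's median was 0.04 (-0.05 with library totals; camera adjusted p = 0.784). Neither the Pel polysaccharide list (0 of 7 members, median 0.07, or -0.02 with library totals) nor the list for cyclic di-GMP and matrix proteins (0 of 19, median -0.05) had a called member, with camera adjusted p of 0.751 and 0.969. In the quinolone signal list, pqsH, which completes the synthesis of the Pseudomonas quinolone signal, fell from 683.7 ± 148.5 to 347.4 ± 52.5 CPM (mean ± SD, n = 2), a log2 fold change of -0.98 ± 0.21 (SE; edgeR adjusted p = 0.0367). The remaining 8 members did not pass, and the list had a median of -0.34 (camera adjusted p = 0.0594). The Las and Rhl regulators (0 of 7 members, median 0.12), the quorum-regulated exoproducts (0 of 18, median 0.00, or -0.09 with library totals) and the phenazine genes (0 of 11, median 0.22) had camera adjusted p of 0.597, 0.701 and 0.464. The phenazine operon is present in near-identical copies, so its counts are uncertain. Glutathione metabolism had 0 of 9 members past the threshold and a median of -0.13 (camera adjusted p = 0.898), with gshA, the first enzyme of glutathione synthesis, at 0.28 ± 0.14 (edgeR adjusted p = 0.275) and the glutathione-degrading enzyme gene ggt at 0.36 ± 0.19 (edgeR adjusted p = 0.285). Cysteine and sulfur assimilation had 0 of 26 members past the threshold (median -0.03, camera adjusted p = 0.898), its regulator gene cysB standing at 0.55 ± 0.18 (edgeR adjusted p = 0.112). The lists for copper (0 of 8 members, median -0.09), zinc starvation (0 of 5, median -0.19), the SOS response (0 of 12, median 0.16), cell division and envelope synthesis (0 of 26, median -0.08) and catabolism of branched-chain and aromatic amino acids (0 of 31, median -0.02) had no member past the threshold, and their camera adjusted p lay between 0.437 and 0.925. The signs of median, mean and camera direction differed for the lists of Psl, exoproducts, sulfur assimilation, amino acid catabolism and cyclic di-GMP, none of which was called. Without GSH replicate 1 or 2 pqsH was no longer called (edgeR adjusted p = 0.0636 and 0.212). The phenazine list was called higher without PBS replicate 1 (median 0.66, camera adjusted p = 0.00716), but its direction turned without PBS replicate 2 (median -0.13, 0.335).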

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

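Of the tests in this part, the one of genomic DNA was set before its result was seen, and those of ribosomal RNA left after depletion, of the PBS samples and of the ribosomal protein genes were chosen only after the pattern was seen. In reads outside the gene counts, GSH replicate 2 had 40.1% in no annotated gene, above both PBS samples (25.6% and 27.8%), while GSH replicate 1 had 18.9%. GSH replicate 1 had 6.45% of reads overlapping several genes, above the PBS samples at 5.58% and 5.10%. Reads of low mapping quality made up 0.491% in GSH replicate 1 and 0.352% in GSH replicate 2, above 0.330% and 0.268% in the PBS samples.

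The GSH samples differed in opposite directions from PBS in the share of reads outside genes, so the share does not go with the treatment. With GSH replicate 1 scaled to the same number of reads in genes, GSH replicate 2 held 7961320 more reads in no annotated gene. Were these genomic DNA, they would put about 1100 counts per kb on every gene. That figure assumes that only reads on a gene's own strand were counted for it, and counting both strands would make it larger. The 294 least expressed genes had a median of 54.7 counts per kb in that sample, against 88.1 in GSH replicate 1. Ribosomal RNA left after depletion could account for the excess reads and cannot be told apart here, since 0 ribosomal RNA features are annotated or counted. No biological explanation was tested.

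Genes that differed between the groups also tended to differ between the PBS samples: 157 of the 186 higher genes were higher in PBS replicate 1 than in PBS replicate 2, and 162 of the 184 lower genes were lower. Whether PBS replicate 2 alone made the calls is not decided by the calls kept without it. That fit takes its spread from the GSH samples alone, which differed less from each other than the PBS samples did. In effect size, the list medians without PBS replicate 2 were 1.11 for pyoverdine and 0.71 for ribosomal proteins, against 1.45 and 0.76 on all samples. Whether the share of reads outside genes shaped the contrast is not decided either. The GSH samples hold the extremes of that share, and their difference correlated at -0.125 across genes with the group difference. This lay within a bound of 0.3, which was set after the pattern was seen. The GSH shares lie on either side of the PBS shares, so such an effect would largely cancel in the group mean and could give only a weak correlation. Cultures may have varied in state along the direction of the treatment. Across genes, PBS replicate 1 minus PBS replicate 2 correlated at 0.432 with the group difference and at 0.0487 with GSH minus PBS replicate 1. The mirrored form of the latter gave -0.689. The last 2 values share a sample with opposite signs, which pulls them below 0 by an unknown amount. The group difference itself holds both PBS samples. A larger deviation of PBS replicate 2 alone, of whatever origin, would therefore raise the 0.432 and the counts of 157 and 162. These values decide nothing. With 2 PBS samples, such a shift and the effect of GSH, the explanation the design names, cannot be told apart for these genes.

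Ribosomal protein genes, with a median log2 fold change of 0.76, are short and abundant, so a length or scaling trend was tested. The 165 other genes matched to them on length and expression had a median of 0.05 (0.0498), which argues against short gene length. With library totals as the only scaling, the median of the ribosomal protein genes was 0.67 (0.670), while that of all genes moved from -0.01 to -0.10. A change of scaling moves all genes by about the same amount, so this value could hardly fall far. It shows only that the choice between these scalings does not account for the rise. A response to GSH remains a hypothesis, found and tested on the same data, and the PBS samples also differed in these genes, by a median of 0.21, against 0.76 in the pyoverdine genes. The 0.21 covers all measured members, and genes named above for their rise differed more. rplW had 158.6 CPM in PBS replicate 1 and 69.4 in PBS replicate 2, rpsC 573.8 and 270.3, and rpsM 422.6 and 343.1.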

How the results depend on the processing

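No called gene changed sign under any alternative run. Both GSH values of each of the 370 called genes lay on the same side of both PBS values. Leaving out a sample or changing the scaling could therefore hardly turn a sign, and kept signs are no sign of robustness. Named genes that did not pass could change sign, such as pchB, pchG and pchF_1 of pyochelin synthesis without PBS replicate 2. The number of genes higher with GSH, 186 in the main test, was 371 in DESeq2, whose lower genes numbered 247 against 184; the cause was not tested. A fold threshold of 2 left 95 higher and 106 lower by construction. Between limma-voom, the other scalings and filters, the robust fit and removal of the 10 most abundant genes, the counts lay between 160 and 196 higher and between 167 and 240 lower. Leaving out each sample in turn gave 60 to 622 higher and 75 to 473 lower genes, 2 to 9 lists higher and 0 to 2 lower. Of the 370 called genes 369 were still called without PBS replicate 1, 307 without PBS replicate 2, 201 without GSH replicate 1 and 128 without GSH replicate 2; these fits have fewer samples, and the lone sample of a group is assumed to vary like the other group. Without PBS replicate 1 there were 622 higher and 473 lower genes and 1 lower list, without PBS replicate 2 there was 1 lower list, without GSH replicate 1 there were 100 lower genes and 2 and 0 lists, and without GSH replicate 2 there were 60 and 75 genes. Camera with an estimated correlation called 0 lists higher and 0 lower (0 at an unadjusted p under 0.05), and fry's directional test 0 and 0 (6 unadjusted). With the replicate number as a replicate block, 249 genes were higher and 203 lower. In that fit 5 lists were higher and 2 lower, type VI secretion being lost (camera adjusted p = 0.0611). Deviations of same-numbered samples correlated at -0.0271 across genes, so no strong shared deviation was seen. A shared day or batch is not stated in the labels, and this value cannot exclude one. Over the alternatives, the named genes gave 2060 values on the same side of the threshold, 99 newly past it and 36 no longer past it, most of these from leaving out a sample. With library totals only, the medians of 5 lists changed sign, none of them called. The alternative that keeps ribosomal and transfer RNA genes was not run, since the counted files hold none. Of changes of 1.5-fold simulated with these library sizes, dispersions and 2 samples per group, 31.6% were called.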

Other observations

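All tests and groupings in this part were chosen only after the results were seen. Genes called in the same direction lay next to each other on the chromosome in 172 pairs. In 10000 shuffles of the gene order the median was 12 and the highest value 25. Shuffling single genes breaks up operons, so this shows only that called genes were not placed independently of each other. Allowing gaps of up to 2 genes, 159 of the 370 called genes fell into 14 blocks of at least 4, 6 of them higher and 8 lower with GSH. Operons would give such pairs and blocks, and whether the pattern goes beyond them was not tested. Outside the pyoverdine, ribosomal and nitrite reductase clusters and the 62.6 kb segment, a pair of blocks hold surface genes. In the rcp and tad genes for assembly of the Flp type of pilus (2863991 to 2871465) 8 of 8 genes fell, with a median log2 fold change of -0.68, among them rcpC at -0.79 ± 0.17, tadA at -0.61 ± 0.14 and tadD at -0.96 ± 0.17 (SE, n = 2). At 2005047 to 2017396, 7 of 7 genes fell, with a median of -0.95: AES1R_01930 and AES1R_01931, annotated as surface adhesion proteins, stood at -0.95 ± 0.13 and -1.03 ± 0.15, and the ABC transporter and secretion protein genes AES1R_01935 and AES1R_01936 at -0.90 ± 0.14 and -0.72 ± 0.13. Without GSH replicate 1, 0 of the 8 pilus genes and 2 of the 7 adhesion genes were called, and without GSH replicate 2, 2 and 1.

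Among smaller blocks, a pair of drug efflux genes rose next to a regulator of the TetR family: AES1R_01581, a putative drug efflux transporter, by 1.13 ± 0.16 and AES1R_01579, annotated as MdtI, by 0.82 ± 0.14 on the log2 scale (4 of 4 genes, 1645383 to 1648021). AES1R_03777 and AES1R_03778, annotated in pyrroloquinoline quinone biosynthesis, rose by 1.52 ± 0.15 and 1.34 ± 0.15, beside RND transporter genes (4 of 6 genes, 3959693 to 3968729). An ABC transporter operon, AES1R_04163 to AES1R_04166, fell in 4 of 4 genes with a median of -0.87. Without GSH replicate 2, 1 of the 4 drug efflux genes, 2 of the 4 quinone block genes and 0 of the 4 ABC transporter genes were called, against 4, 3 and 2 without GSH replicate 1. Of 774 tests of words in product names, 4 passed: ribosomal among higher genes (24 of 74 genes, Fisher's exact test, adjusted p = 8.32e-16), protein among higher (106 of 2358, 7.57e-04) and lower genes (100 of 2358, 0.0110), and hypothetical among lower genes (48 of 853, 0.00570). The last 3 name no function. Fisher's test takes genes as independent, but 21 of the higher genes with the word ribosomal lay in a single cluster (5314528 to 5326341). Its p-value is therefore too small by an unknown amount. These genes largely repeat the ribosomal protein list, so the word adds no separate support. The stress protein gene osmC fell by 1.69 on the log2 scale (SE 0.20; edgeR adjusted p = 0.00383).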
